A study of Mus musculus with 24 samples.

How the data were processed

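The analysis started from 1 table of raw read counts per gene, deposited by the authors, with 43629 Ensembl gene identifiers as rows and the 24 libraries as columns. The unit of its values is count, per the labels and the deposited values, which are whole numbers whose sums differ between libraries. No column was left unused. Per the labels' protocols, cells received DMSO, 2.5 µM RG6146, 10 ng/mL TNF or both for 3 h, and libraries were made from 500 ng of RNA with the QuantSeq 3′ kit, primed with oligo-dT, and read as single ends of 75 bp on a NextSeq 500. Per the submitters' processing notes, reads were demultiplexed with bcl2fastq 2.17.1.14, trimmed with cutadapt 1.14, aligned to mm10 with HISAT2 2.1.0 and counted with featureCounts of Subread 1.5.2, and limma was used for the authors' own tests. The annotation release, the strand setting, the treatment of reads that map to several places and any use of molecular barcodes are not given in the sources used here. What a replicate number shares, how RNA quality was measured and the number of mapped reads are not given in the sources used here either. The growth protocol for all samples names MC38-Ova cells, while the sample labels name E0771 and MC38, and the labels were followed.

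Symbols came from a separate reference list of gene names, which held 42462 of the identifiers. Positions, strands, gene types, transcript lengths and exon overlaps came from GENCODE vM21 on GRCm38 (mm10), in which 42548 of the identifiers were found. Because the strand setting is unknown, genes with an exon of another gene on the opposite strand can hold its reads. Oligo-dT priming reaches polyadenylated transcripts, so most replication-dependent histone transcripts are outside its reach, and histone values rest on polyadenylated forms and on how near-identical copies were counted.

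The tests, gene lists, rule for naming genes and most alternatives were fixed before the data were examined. Software was R 4.3.3 with edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and Biostrings 2.70.1, and Python 3.11.15 with numpy 2.4.6 and matplotlib 3.10.9. Each line was fitted apart, with its 12 libraries in 4 groups of 3 and no covariate. Genes were kept by edgeR's filterByExpr with the groups, which left 12541 in E0771 and 13272 in MC38, and libraries were scaled with TMM factors. Dispersions came from estimateDisp, and contrasts of group means were tested two-sided with edgeR's quasi-likelihood F test (glmQLFit and glmQLFTest). P-values were adjusted by the Benjamini-Hochberg method over the tested genes, and a gene was called at an adjusted p under 0.05. The interaction was the combination minus RG6146 less TNF minus DMSO. Differences between lines were the effect in E0771 minus that in MC38, tested in 1 fit of all 24 libraries and 14058 genes. Fold changes are edgeR's with a prior count of 0.125. SE is the absolute log2 fold change divided by the root of the F statistic. CPM are counts scaled by TMM to a common library total (cpm of edgeR), given as mean ± SD of 3 libraries, and library quality values, the sums of markers among them, are shares of the raw counts.

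The 23 gene lists were tested with edgeR's camera at a preset inter-gene correlation of 0.01, two-sided, where at least 3 members passed the filter, and adjusted over the lists of a comparison. The lists are NF-kB feedback regulators, chemokines and cytokines, survival genes, death receptor and apoptosis genes, TNF receptor complex, adhesion molecules and metalloproteases, immediate early genes, interferon-stimulated genes, antigen presentation, checkpoint ligands, MYC and ribosome biogenesis, BET inhibitor-induced markers, BET and P-TEFb components, cell cycle genes, p53 targets, unfolded protein and integrated stress response, cholesterol synthesis, TGF-beta and matrix genes, mitochondrially encoded genes, and leukocyte, fibroblast, endothelial and epithelial markers. They were written from general knowledge and not from these data. Counts of members called are given over all tested genes, and for part of the lists also adjusted over the list alone. TNF-induced sets were genes with an adjusted p under 0.05 and a log2 fold change of at least 1 for TNF against DMSO in 1 line, tested in the other.

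Genes were named by rule. In each comparison of TNF or RG6146 with DMSO, of the combination with TNF, and in the interaction, the rule took the 6 largest increases and 6 largest decreases among called genes with a mean count of at least 20 and, for pairs of groups, no overlap between the groups, passing over predicted genes and clone names. It also took the 2 called members of each list with the smallest p in each direction, and genes fixed in advance whatever their result, among them Nfkbia, Tnfaip3, Birc3, Cflar, Cxcl1, Ccl2, Cxcl10, Icam1, Relb, Cd274, Myc and Hexim1. After the data were seen it was applied to the differences between lines as well. The text prints part of the genes it gave. Birc3 did not pass the filter in E0771.

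The calling was tested on simulated data: for each comparison negative binomial counts were drawn with the totals and gene-wise dispersions of the fit and equal means in all groups, and changes of 1 or 2 on the log2 scale were put into 200 genes of 1 group. In E0771 the test recovered 75.2% and 96.9% for TNF against DMSO (12400 genes), 77.1% and 96% for RG6146 against DMSO (12379), 79.2% and 97.9% for the combination against DMSO (12387), 69.4% and 95.5% for the combination against TNF (12384), 68.1% and 93.4% for the combination against RG6146 (12383) and 53.8% and 93.3% for the interaction (12387). In MC38 it recovered 59% and 90.5% (13121 genes), 61.2% and 91.8% (13105), 57.4% and 90.4% (13115), 51.5% and 86.5% (13110), 64.4% and 92.6% (13118), and 24.3% and 71.3% for the interaction (13118), in the same order. For the differences between lines it recovered 34.7% and 78.4% for TNF (13606) and 28.9% and 66.7% for RG6146 (13572).

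The alternatives were RLE size factors, library totals alone, no filter beyond 1 count in any library, a filter of 5 CPM in 3 libraries, the DESeq2 Wald test, limma-voom, only the 6 libraries compared, the replicate number as a block, each library left out in turn, an estimated inter-gene correlation, and sets chosen in the same line or with other fold minimums. Added after the data were seen were the libraries that stood apart left out (in each group the library farthest from the other 2, at a root mean square log2 distance above 0.45) and limma-voom with sample quality weights. Named genes were recomputed under the alternatives for gene tests except sample quality weights. Lists were recomputed with RLE size factors, library totals, both other filters and the estimated correlation. No sequence reads were reprocessed, and the authors' own test results and any other dataset were left out.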

Results

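Gene expression was measured in 2 mouse tumour cell lines, E0771 from a breast adenocarcinoma and MC38 from a colon adenocarcinoma. Cells were treated for 3 h with DMSO (the solvent control), with 2.5 µM RG6146, with 10 ng/mL TNF, or with RG6146 and TNF together, called the combination here. RG6146 inhibits BET bromodomains, protein domains that bind acetylated histones. TNF is a cytokine that activates the transcription factor NF-kB and can also start cell death. Each line and treatment had 3 replicates, which gave 24 libraries made with a kit that reads the 3′ ends of polyadenylated transcripts. The deposited gene counts summed to between 5392406 and 9132814 per library in E0771 and between 5392808 and 9673118 in MC38. The labels do not say that replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. Values below are log2 fold changes ± SE with 3 libraries in each group unless another unit is named.

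Several libraries stood apart from the others of their group. Mitochondrial ribosomal RNA made up 0.376% of the counts in E0771 TNF replicate 2 and 0.609% in MC38 DMSO replicate 2, against 1.685% to 3.227% in the other 22 libraries. MC38 TNF replicate 1 and MC38 combination replicate 2 also lay far from the other libraries of their groups. These 4 are the libraries said below to stand apart, 1 per group at most. E0771 TNF replicate 3 and MC38 DMSO replicate 3 also exceeded the limit of 0.45. Their root mean square log2 distances were 0.546 and 0.532, against 0.468 for MC38 combination replicate 2. In MC38 combination replicate 2 the leukocyte markers summed to 1890 CPM, against 5.75 to 33.6 CPM in the other MC38 libraries and 116 to 206 CPM in E0771.

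**Figure D1:**
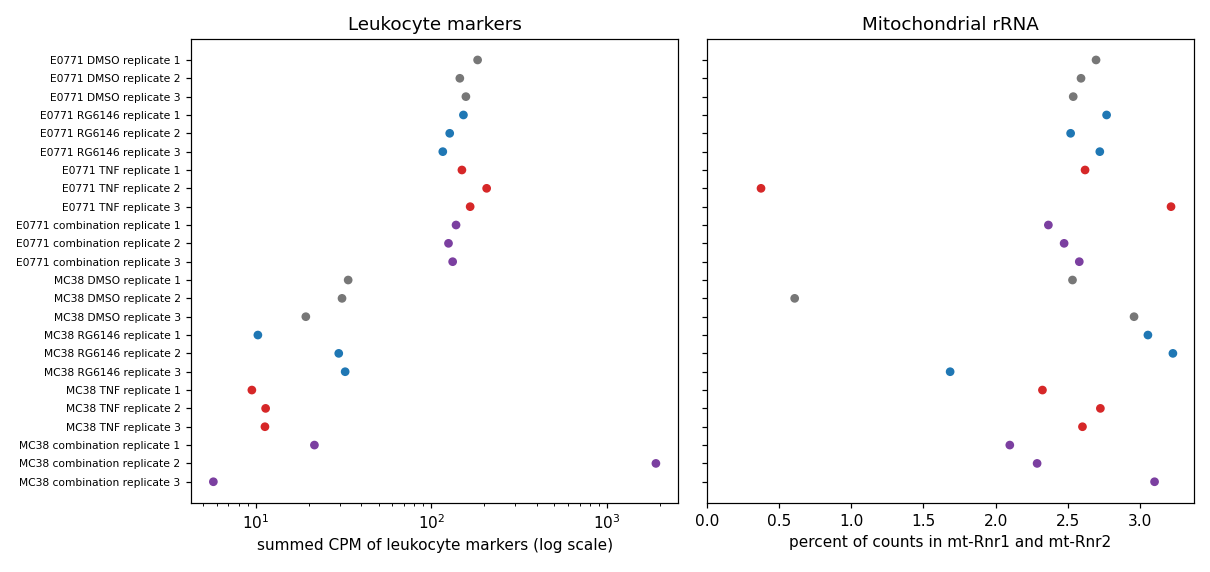
Each point is 1 of the 24 libraries, coloured by treatment (grey DMSO, blue RG6146, red TNF, purple combination), with the summed CPM of leukocyte markers on a log axis at the left and the percent of counts in the mitochondrial ribosomal RNAs at the right. MC38 combination replicate 2 lies at 1890 CPM of leukocyte markers, and E0771 TNF replicate 2 and MC38 DMSO replicate 2 lie at 0.376% and 0.609% mitochondrial ribosomal RNA.

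The comparison of TNF with DMSO asked which transcripts responded to the cytokine. In E0771, TNF raised genes of chemokines, adhesion molecules and inhibitors of NF-kB. Nfkbia, which encodes the NF-kB inhibitor IκBα, rose 11.4-fold (3.51 ± 0.09, adjusted p = 8.33e-12), from 354 ± 23.3 CPM with DMSO to 4040 ± 276 CPM with TNF (mean ± SD, n = 3). The neutrophil chemokine genes Cxcl2 and Cxcl1 rose by 5.63 ± 0.34 and 4.66 ± 0.32, the adhesion genes Icam1 and Vcam1 by 4.30 ± 0.22 and 3.86 ± 0.16, and the monocyte chemokine gene Ccl2 by 2.59 ± 0.36. Id1 and Id2, inhibitors of helix-loop-helix transcription factors, changed by -1.99 ± 0.16 and -1.86 ± 0.10. On mm10, Nfkbia lies on chromosome 12 at 55489410 to 55492647, Ccl2 on chromosome 11 at 82035571 to 82037453, Cxcl1 on chromosome 5 at 90891241 to 90893115 and Id2 on chromosome 12 at 25093799 to 25097140. All 4 are protein-coding genes with no exon of another gene over theirs, whereas Icam1 and Vcam1 each overlap an exon of a gene on the opposite strand, so their counts can include its reads.

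Of the 16 tested NF-kB feedback regulators, 11 rose with TNF in E0771 (14 adjusted over the list alone), among them Nfkbie at 4.26 ± 0.29, Tnfaip3 at 3.11 ± 0.45 and Relb at 2.04 ± 0.16. Of 13 chemokines and cytokines, 11 rose (12 adjusted over the list alone). Among 13 survival genes 6 rose and 7 were not called (7 rose adjusted over the list alone), with Traf1 at 1.86 ± 0.16 and Ier3 at 1.27 ± 0.09, while Cflar, an inhibitor of caspase-8, stood at 0.02 ± 0.13. Among 14 adhesion molecules and metalloproteases 5 rose (10 adjusted over the list alone), and among 16 p53 targets 5 rose (8 adjusted over the list alone), Mdm2 by 1.06 ± 0.10. In the list of 19 death receptor and apoptosis genes 3 rose and 16 were not called (4 rose adjusted over the list alone), with the death receptor gene Fas at 2.74 ± 0.24 and Bcl2l11 at 0.71 ± 0.10. Of 17 unfolded protein and stress response genes 2 rose (3 adjusted over the list alone), Atf3 by 1.18 ± 0.17 and Herpud1 by 0.67 ± 0.11. The list of 30 MYC and ribosome biogenesis genes rose as a set with 2 members called (3 adjusted over the list alone) and a median of 0.15, and Myc itself stood at 0.18 ± 0.26. These 8 lists passed the camera test with the preset and with an estimated correlation (largest adjusted p = 0.032 with an estimated correlation).

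Immediate early genes rose as a set in E0771 with TNF, with 8 of 25 higher, 1 lower and 16 not called (10 higher and 4 lower adjusted over the list alone). Junb rose by 2.22 ± 0.18 and Klf2 changed by -0.72 ± 0.13, a call that ended without DMSO replicate 3 (adjusted p = 0.0507), and the set had adjusted p = 3.96e-06, and adjusted p = 0.0894 with an estimated correlation. The BET inhibitor-induced markers were lower as a set (adjusted p = 0.0103, and adjusted p = 0.0506 with an estimated correlation), with Hexim1 at -0.59 ± 0.11 the 1 of 9 that fell. Hexim1 encodes an inhibitor of the elongation kinase P-TEFb, and its call ended without DMSO replicate 2 (-0.57, adjusted p = 0.0572). TGF-beta and matrix genes were higher as a set (3 of 15 rose, adjusted p = 0.0395, and adjusted p = 0.131 with an estimated correlation). The set of cell cycle genes was lower with a median of -0.12 and 29 of 29 members not called (adjusted p = 0.0479, and adjusted p = 0.178 with an estimated correlation). The mitochondrially encoded genes were lower as a set (adjusted p = 0.0217, and adjusted p = 0.0599 with an estimated correlation), with mt-Nd6 at -1.41 ± 0.18 the 1 of 13 that fell. TNF replicate 2 is the library low in mitochondrial ribosomal RNA, and the opposite strand of mt-Nd6 carries another mitochondrial gene.

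The other lists were not called with TNF in E0771. In the TNF receptor complex Rela and Tnfrsf1b rose among 17 genes, and in the interferon-stimulated list 3 of 28 rose, with Irf1 at 2.75 ± 0.10. The median of the interferon-stimulated list was -0.13 while its mean and its test were positive (0.07, adjusted p = 0.103). Antigen presentation genes had 18 of 18 members not called, and checkpoint ligands had 1 of 9 higher, with Cd274, which encodes PD-L1, at 0.00 ± 0.29. BET and P-TEFb components had 1 of 15 higher, and cholesterol synthesis genes had 18 of 18 not called. Markers of other cell types were few: 6 leukocyte and 3 endothelial markers passed the filter with none called, Pdgfrb was the 1 of 3 fibroblast markers that rose, and the single epithelial marker was too few for a test.

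In all, edgeR's quasi-likelihood test called 291 of 12541 genes in E0771, 236 higher and 55 lower, a share higher of 81.1% that became 67.4% when libraries were scaled by their totals alone. The count was 188, 164 and 192 without DMSO replicate 1, 2 or 3, 622 without TNF replicate 1, 110 in a fit of the 6 libraries compared and 524 without the filter on low counts.

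In MC38 the same comparison raised chemokine, NF-kB and survival genes. Nfkbia rose by 3.46 ± 0.13 (adjusted p = 2.38e-09), from 265 ± 29.1 to 2910 ± 145 CPM. Ccl2 rose by 4.82 ± 0.61, Cxcl1 by 4.71 ± 0.33, Cxcl10, which attracts T cells, by 3.60 ± 0.26 and the cytokine gene Lif by 5.87 ± 0.86. Fas rose by 3.80 ± 0.42, Tnfaip3, which encodes the NF-kB inhibitor A20, by 5.03 ± 0.66, and the inhibitor of apoptosis genes Birc3 and Birc2 by 2.15 ± 0.33 and 1.68 ± 0.18. Lif and Tnfaip3 rested on 5 and 6 counts over the 3 DMSO libraries. Icam1 stood at 4.40 ± 1.01 (adjusted p = 0.0547), with 1 count in the 3 DMSO libraries and 27 in the 3 TNF libraries. Fas lies on chromosome 19 at 34290666 to 34327772, Tnfaip3 on chromosome 10 at 19000910 to 19015657 and Birc3 on chromosome 9 at 7848699 to 7873186 (mm10), and an exon of Art3 lies opposite Cxcl10.

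In MC38 9 of 16 NF-kB feedback regulators rose with TNF (14 adjusted over the list alone), with Nfkbie at 2.90 ± 0.17 and Relb at 1.35 ± 0.16. Of 12 chemokines and cytokines 8 rose and 4 were not called (9 rose adjusted over the list alone). Of 14 survival genes 6 rose (9 adjusted over the list alone), with Gadd45b at 1.95 ± 0.17, and Cflar stood at 0.62 ± 0.14 (adjusted p = 0.0538). Immediate early genes had 9 of 26 higher (16 higher and 1 lower adjusted over the list alone), with Junb at 2.70 ± 0.18 and Ier5 at 1.55 ± 0.14. Among p53 targets 5 of 17 rose (7 adjusted over the list alone), with Cdkn1a at 1.81 ± 0.18. Vcam1 at 2.18 ± 0.13 was the 1 of 13 adhesion molecules and metalloproteases that rose (6 adjusted over the list alone), and Tapbpl at 1.09 ± 0.19 the 1 of 19 antigen presentation genes (3 adjusted over the list alone). The call of Tapbpl ended without DMSO replicate 2 (adjusted p = 0.0546). These 7 lists passed camera with both correlations (largest adjusted p = 0.00846 with an estimated correlation).

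The TNF receptor complex was higher as a set in MC38 with Birc2 and Birc3 called among 18 genes (adjusted p = 0.00348, and adjusted p = 0.0548 with an estimated correlation). Interferon-stimulated genes had 2 of 27 higher, with Irf1 at 2.02 ± 0.21 (adjusted p = 0.00498, and adjusted p = 0.381 with an estimated correlation). Checkpoint ligands had 2 of 8 higher (adjusted p = 0.0365, and adjusted p = 0.173 with an estimated correlation), while Cd274 stood at 1.64 ± 0.46 (adjusted p = 0.129). TGF-beta and matrix genes had 1 of 14 higher (adjusted p = 0.0426, and adjusted p = 0.173 with an estimated correlation). The remaining tested lists were not called, and Myc at 1.46 ± 0.53 and Hexim1 at 0.08 ± 0.18 were not called either. In the MYC and ribosome biogenesis list the median and mean were above 0 while the test pointed down (adjusted p = 0.921). With 2 endothelial and no epithelial markers past the filter, those lists had no test in MC38. The test called 145 of 13272 genes, 136 higher and 9 lower. The count was 95 without DMSO replicate 2, 69 with the 6 libraries compared, 305 with DESeq2 and 574 without the filter.

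**Figure D2:**
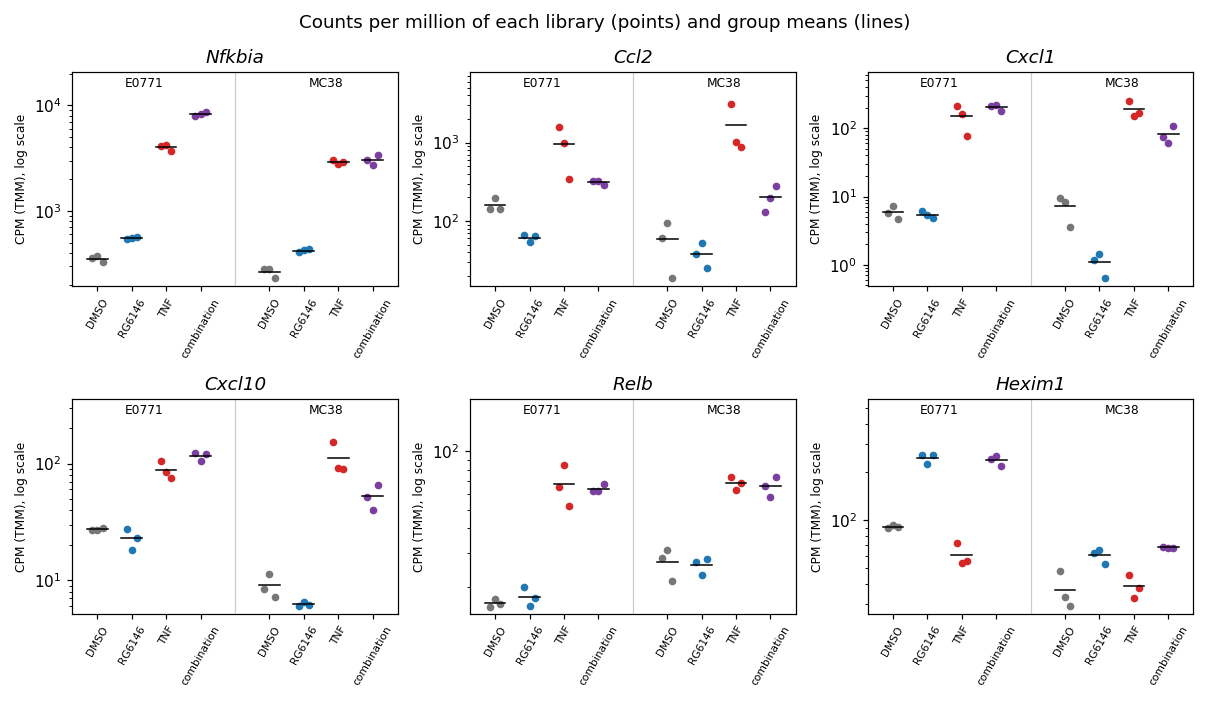
Each point is a library's CPM after TMM scaling on a log axis, and each black line is the mean of the 3 libraries of a treatment, for 6 genes in E0771 (left of the grey line) and MC38 (right of it). Mean Nfkbia was 4040 CPM with TNF and 8280 CPM with the combination in E0771, against 2910 and 3030 CPM in MC38.

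Both lines raised many of the same genes with TNF: 70 genes tested in both were higher in both, against 2.16 for independent lists, and 3 were lower in both, Id1 and Id2 among them, against 0.0249. In MC38 the call of Id1 (-1.70 ± 0.31) ended without DMSO replicate 1 or TNF replicate 2 (adjusted p = 0.0645 and 0.0573), and that of Id2 (-1.93 ± 0.39) without DMSO replicate 1 or 2 or TNF replicate 2 or 3 (adjusted p = 0.0757 to 0.107). The test of the difference between the lines called 29 of 14058 genes. The chemokine gene Cxcl10 responded less in E0771 than in MC38 (difference -1.85 ± 0.29, adjusted p = 0.00469), whereas Vcam1, Tnfaip2, the prostaglandin synthase gene Ptges and the adenosine receptor gene Adora2b responded more in E0771 (1.72 ± 0.20, 1.29 ± 0.15, 1.94 ± 0.20 and 2.17 ± 0.28). Nfkbia did not pass (0.10 ± 0.14, adjusted p = 0.776). As sets, NF-kB feedback regulators and adhesion molecules and metalloproteases responded more in E0771 with both correlations (adjusted p = 0.0189 and adjusted p = 0.0374 with an estimated correlation). The chemokine list had the more positive response in MC38 (adjusted p = 0.0179, and adjusted p = 0.301 with an estimated correlation), as did immediate early genes (adjusted p = 0.0179, and adjusted p = 0.342 with an estimated correlation), while the MYC and ribosome biogenesis list had it in E0771 (adjusted p = 0.0179, and adjusted p = 0.301 with an estimated correlation). Of the 29 genes 41.4% had the more positive response in E0771, and 24.3% of those called with library totals alone. The count was 327 without E0771 TNF replicate 1, 76 without MC38 TNF replicate 3, 8, 7 and 12 without E0771 DMSO replicate 1, 2 or 3, 9 without E0771 TNF replicate 2, and 19 and 16 without MC38 DMSO replicate 1 or 2. It was 182 with DESeq2 and 514 without the filter.

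The comparison of RG6146 with DMSO asked what BET inhibition did without TNF. In E0771, RG6146 raised histone genes and Hexim1, transcripts known to rise with BET inhibitors. Hist1h1c rose by 2.59 ± 0.09 (adjusted p = 1e-09), from 87.3 ± 2.17 to 526 ± 24.2 CPM, Hist1h2bc by 2.74 ± 0.11 and Hexim1 by 1.42 ± 0.11. Among the decreases were Runx1t1 at -3.29 ± 0.31, Prdm1 at -2.64 ± 0.17, which encodes the repressor BLIMP1, and Hoxa10 at -2.43 ± 0.28. Brd2, a BET gene, rose by 1.67 ± 0.20, and Myc stood at 0.15 ± 0.26, not called. Hist1h1c lies on chromosome 13 at 23738808 to 23740367, Hexim1 on chromosome 11 at 103116231 to 103119725 and Prdm1 on chromosome 10 at 44437177 to 44528501 (mm10). Histone genes have near-identical copies, so reads can be split between them, and exons of H2-DMa lie opposite Brd2.

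Of 9 BET inhibitor-induced markers 6 rose in E0771 with RG6146 (the same number adjusted over the list alone). Of 17 unfolded protein and stress response genes 9 rose and 1 fell (11 and 1 adjusted over the list alone), with the stress transcription factor gene Ddit3 at 0.98 ± 0.11, Atf3 at 1.24 ± 0.17 and Trib3 at -0.62 ± 0.11. Of 28 interferon-stimulated genes 11 fell and 17 were not called (15 fell adjusted over the list alone), with Irf9 at -0.91 ± 0.11 and Ifit1 at -0.94 ± 0.12. Of 13 survival genes 4 fell and 1 rose (7 and 1 adjusted over the list alone), with Bcl2l1, which encodes BCL-XL, at -1.22 ± 0.12, Traf1 at -1.33 ± 0.20 and Gadd45b at 0.80 ± 0.16. These 4 lists passed camera with both correlations (largest adjusted p = 0.0246 with an estimated correlation).

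Chemokines and cytokines were lower as a set in E0771 with RG6146, Ccl7 at -1.82 ± 0.26 and Ccl2 at -1.39 ± 0.37 being the 2 of 13 that fell (4 adjusted over the list alone; adjusted p = 0.00405, and adjusted p = 0.236 with an estimated correlation). The call of Ccl2 ended without DMSO replicate 1 or 2 or without any RG6146 replicate (adjusted p = 0.0526 to 0.0967). Immediate early genes were higher as a set, with 8 of 25 higher and 4 lower (9 and 5 adjusted over the list alone), Klf2 at 2.40 ± 0.13 and Fosl1 at -0.76 ± 0.10 (adjusted p = 4.75e-05, and adjusted p = 0.185 with an estimated correlation). Of 3 fibroblast markers Pdgfra and Pdgfrb, growth factor receptor genes, fell by 1.05 and 1.16 on the log2 scale (adjusted p = 0.00405, and adjusted p = 0.159 with an estimated correlation).

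Among the lists not called in E0771 with RG6146, NF-kB feedback regulators held 1 gene that rose, Nfkbia at 0.65 ± 0.08, and 1 that fell, Traf1. Death receptor and apoptosis genes had 1 of 19 higher and 4 lower, with Casp8 at -1.06 ± 0.21, and the TNF receptor complex had 3 of 17 lower. Cell cycle genes had 6 of 29 lower, with Cdt1 at -0.68 ± 0.09, MYC and ribosome biogenesis genes 5 of 30 lower, and p53 targets 2 of 16 higher and 4 lower. BET and P-TEFb components had 2 of 15 higher and 1 lower, antigen presentation 2 of 18 higher, checkpoint ligands 2 of 9 lower and cholesterol synthesis 1 of 18 higher, Insig1 at 0.94 ± 0.16. Adhesion molecules, TGF-beta and matrix genes, mitochondrially encoded genes and leukocyte and endothelial markers had no call. The test called 1357 genes, 497 higher and 860 lower, 36.6% higher and 26.5% higher with library totals alone. The count was 837 and 881 without DMSO replicate 1 or 3, and 821, 870 and 728 without RG6146 replicate 1, 2 or 3. It was 2333 without E0771 TNF replicate 2, which shares in the estimate of the spread. With the 6 libraries compared it was 3108, nearly balanced at 1533 higher and 1575 lower.

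In MC38, RG6146 raised Hist1h2bc by 2.60 ± 0.18, Hist1h1c by 1.69 ± 0.13, Il20rb by 2.24 ± 0.24 and Brd2 by 1.57 ± 0.19. It lowered Prdm1 (-2.52 ± 0.32), the chemokine gene Cxcl1 (-2.70 ± 0.45), the insulin receptor substrate gene Irs1 (-2.52 ± 0.26) and Cd300lb (-2.66 ± 0.17, adjusted p = 4.78e-06). Nfkbia rose by 0.67 ± 0.12. Hexim1 rose by 0.72 ± 0.18 (adjusted p = 0.0241), a call that ended without DMSO replicate 2 or 3 or RG6146 replicate 1 or 2 (adjusted p = 0.0533 to 0.108). Myc stood at -0.39 ± 0.56, not called. Of 9 BET inhibitor-induced markers 5 rose, and of 18 unfolded protein and stress response genes 6 rose and 12 were not called (8 rose adjusted over the list alone), with Ddit3 at 1.74 ± 0.15 and Chac1 at 1.67 ± 0.21. Both lists passed camera with both correlations (largest adjusted p = 0.00205 with an estimated correlation).

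Chemokines and cytokines were lower as a set in MC38 with RG6146, 4 of 12 having fallen (5 adjusted over the list alone; adjusted p = 0.00155, and adjusted p = 0.0825 with an estimated correlation). Immediate early genes had 5 of 26 higher and 2 lower, with Egr1 at 1.55 ± 0.20 and Fosl1 at -0.82 ± 0.14 (adjusted p = 0.00327, and adjusted p = 0.356 with an estimated correlation). Interferon-stimulated genes had 4 of 27 lower and 1 higher (adjusted p = 0.00624, and adjusted p = 0.467 with an estimated correlation). BET and P-TEFb components had 1 of 16 higher, Brd2, and 1 lower (adjusted p = 0.0108, and adjusted p = 0.0825 with an estimated correlation). Of 4 fibroblast markers 2 fell, Pdgfra by 1.28 on the log2 scale (adjusted p = 0.00624, and adjusted p = 0.155 with an estimated correlation). Among lists without a call, NF-kB feedback regulators had 2 of 16 higher and 2 lower, with Bcl3 at -2.10 ± 0.33, survival genes had 1 of 14 higher and 2 lower, and death receptor and apoptosis genes had Bcl2l11, which encodes the killer protein BIM, at 1.53 ± 0.19 and 1 gene lower. Vcam1 fell by 0.83 among 13 adhesion genes. Cholesterol synthesis had 3 of 19 higher, cell cycle 2 of 29 lower, p53 targets 2 of 17 higher and 3 lower, MYC and ribosome biogenesis 2 of 30 lower, TGF-beta and matrix genes 1 of 14 higher and 2 lower, and checkpoint ligands 1 of 8 lower. The test called 1098 genes, 447 higher and 651 lower, 40.7% higher, against 27.8% with library totals alone and 48% with RLE size factors, while DESeq2 called 677 higher and 614 lower. The count was 706 without DMSO replicate 1, 620, 479 and 588 without RG6146 replicate 1, 2 or 3, and 1659 with sample quality weights.

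The lines shared 156 genes raised by RG6146, against 17.3 for independent lists, and 257 lowered, against 33.4. The test of the difference called 54 genes. The H1 histone gene Hist1h1c and the tubulin gene Tubb3 rose more in E0771 (0.87 ± 0.15 and 2.09 ± 0.32), and the growth factor gene Ereg and Il20rb had the more positive response in MC38 (-1.97 ± 0.22 and -1.82 ± 0.28). The BET inhibitor-induced markers responded more in E0771 as a set, with 1 of 10 called and 4 adjusted over the list alone (adjusted p = 0.00557 with an estimated correlation). Of the 54 genes 33.3% had the more positive response in E0771, 43.8% with RLE size factors and 44.2% with library totals alone. The count was 24, 27 and 35 without E0771 DMSO replicate 1, 2 or 3, 29, 29 and 30 without E0771 RG6146 replicate 1, 2 or 3, 31, 34 and 88 without MC38 DMSO replicate 1, 2 or 3, and 31 without MC38 RG6146 replicate 2 or 3. It was 116 without the libraries that stood apart, 129 with DESeq2 and 180 without the filter, the last with 117 more positive in E0771 and 63 in MC38.

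The comparison of the combination with TNF asked how BET inhibition changed the state of TNF-treated cells. In E0771, Nfkbia rose a further 2.05-fold (1.04 ± 0.08, adjusted p = 1.72e-06), to 8280 ± 335 CPM, while several TNF-induced genes were lower. Traf1, which encodes a TNF receptor adaptor, stood at -2.34 ± 0.17, the cytokine gene Il15 at -2.04 ± 0.31, Ccl2 at -1.63 ± 0.35, Fas at -1.62 ± 0.22, Vcam1 at -1.48 ± 0.14 and the metalloprotease gene Mmp9 at -1.30 ± 0.19, all lower with the combination. Ccl2 was spread widely with TNF, from 342 CPM in replicate 3 to 1560 CPM in replicate 1, against 287 to 325 CPM with the combination. Cxcl1 (0.43 ± 0.25), Tnfaip3 (0.27 ± 0.34), Cxcl10 (0.39 ± 0.14, adjusted p = 0.0691) and Relb (-0.08 ± 0.15) were not called, and without TNF replicate 1 Cxcl1 and Cxcl10 were called higher (0.76 and 0.53, adjusted p = 0.0336 and 0.0154). Hexim1 rose by 1.97 ± 0.12, Klf2 by 2.83 ± 0.14 and Hist1h2bc by 2.79 ± 0.11, and Prdm1 changed by -2.87 ± 0.16. Cd274 was lower (-1.08 ± 0.33, adjusted p = 0.0399), a call that ended without TNF replicate 1 or 3, without any combination replicate (adjusted p = 0.0614 to 0.154) and with limma-voom or DESeq2 (adjusted p = 0.0587 and 0.102).

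In that comparison in E0771, 5 of 13 survival genes fell and 1 rose (6 and 1 adjusted over the list alone), with Bcl2l1 at -1.22 ± 0.12 and Tnfaip8 and Mcl1 also lower. Of 14 adhesion molecules and metalloproteases 6 fell (9 fell and 1 rose adjusted over the list alone). Of 28 interferon-stimulated genes 11 fell (13 fell and 1 rose adjusted over the list alone), with Irf9 at -1.11 ± 0.11 and Ifit3 at -1.18 ± 0.13, and of 30 MYC and ribosome biogenesis genes 9 fell (10 adjusted over the list alone), with Polr1b at -0.84 ± 0.11. Unfolded protein and stress response genes had 10 of 17 higher and 1 lower (11 and 1 adjusted over the list alone), with Sesn2 at 1.01 ± 0.11, and immediate early genes had 11 of 25 higher and 3 lower (12 and 3 adjusted over the list alone), with Jund at 1.85 ± 0.09 and Fosl2 at -1.19 ± 0.12. Of 9 BET inhibitor-induced markers 7 rose. The mitochondrially encoded genes were higher as a set with 2 of 13 called (7 adjusted over the list alone), and the TNF group held the library at 0.376% mitochondrial ribosomal RNA. These 8 lists passed camera with both correlations (largest adjusted p = 0.0314 with an estimated correlation).

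Chemokines and cytokines were lower as a set, with 7 of 13 lower (8 lower and 2 higher adjusted over the list alone; adjusted p = 0.00376, and adjusted p = 0.183 with an estimated correlation). The p53 targets had 6 of 16 lower and 2 higher, with Mdm2 at -1.45 ± 0.11 (adjusted p = 0.0148, and adjusted p = 0.183 with an estimated correlation), and of 3 fibroblast markers Pdgfra and Pdgfrb fell (adjusted p = 0.0129, and adjusted p = 0.169 with an estimated correlation). Among the lists without a call, NF-kB feedback regulators had 4 of 16 lower and 2 higher, death receptor and apoptosis genes 4 of 19 lower and 2 higher, the TNF receptor complex 5 of 17 lower and 1 higher, cell cycle genes 6 of 29 lower, checkpoint ligands 2 of 9 lower, cholesterol synthesis and BET and P-TEFb components 2 higher each, TGF-beta and matrix genes 2 higher and 2 lower, and antigen presentation 3 higher and 3 lower. The median of the cell cycle list was 0.04 and that of the antigen presentation list 0.01, while their means and tests were negative. The test called 2079 genes in E0771, 893 higher and 1186 lower. The count was 1266 without combination replicate 2 and 881 with the 6 libraries compared.

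In MC38 the combination lowered chemokine, cytokine and survival genes that TNF had raised, while Nfkbia stood at 0.06 ± 0.12 (3030 ± 320 against 2910 ± 145 CPM), not called. Ccl2 changed by -3.04 ± 0.56 (adjusted p = 0.0038), from 1660 ± 1240 to 202 ± 74.7 CPM, Lif by -3.60 ± 0.68, Fas by -3.35 ± 0.41, Il15 by -2.66 ± 0.28, Tnfaip3 by -2.58 ± 0.52 and Cxcl10 by -1.09 ± 0.22. The inhibitor of apoptosis genes Birc3 and Birc2 changed by -1.84 ± 0.33 and -1.20 ± 0.18. Ch25h, the cholesterol 25-hydroxylase gene, changed by -5.09 ± 0.82 and the hyaluronan synthase gene Has2 by -3.20 ± 0.37, and Klf2 rose by 2.52 ± 0.26. Several TNF values were spread widely, Ccl2 from 869 to 3090 CPM, with the highest in TNF replicate 1. Cxcl1 was lower (-1.23 ± 0.28), a call that ended without combination replicate 1 or 2 (adjusted p = 0.0573 and 0.0628). Cd274 was lower (-1.65 ± 0.46, adjusted p = 0.0346), a call that ended without any 1 of the 6 libraries (adjusted p = 0.0506 to 0.113).

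Of 12 chemokines and cytokines 9 fell in MC38 (10 adjusted over the list alone), and of 14 survival genes 6 fell and 1 rose (7 and 1 adjusted over the list alone), with Traf1 at -1.67 ± 0.13 and Gadd45b at 0.96 ± 0.15. Of 17 p53 targets 4 fell and 1 rose (7 and 1 adjusted over the list alone), with Eda2r at -2.00 ± 0.18. Unfolded protein and stress response genes had 5 of 18 higher and 1 lower (7 and 2 adjusted over the list alone), with Ddit3 at 1.63 ± 0.15, cholesterol synthesis genes 3 of 19 higher and 1 lower (7 and 1 adjusted over the list alone), BET inhibitor-induced markers 5 of 9 higher and BET and P-TEFb components 3 of 16 higher (4 adjusted over the list alone). These 7 lists passed camera with both correlations (largest adjusted p = 0.0453 with an estimated correlation).

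NF-kB feedback regulators were lower as a set in MC38, with 4 of 16 lower (adjusted p = 0.00328, and adjusted p = 0.0585 with an estimated correlation). Antigen presentation genes had 6 of 19 lower, Tapbpl at -1.11 ± 0.19 among them (adjusted p = 0.0304, and adjusted p = 0.0681 with an estimated correlation). Interferon-stimulated genes had 3 of 27 lower (adjusted p = 0.0178, and adjusted p = 0.423 with an estimated correlation), immediate early genes 6 of 26 higher and 3 lower (adjusted p = 0.00404, and adjusted p = 0.296 with an estimated correlation), and 4 of 4 fibroblast markers fell (adjusted p = 0.000291, and adjusted p = 0.0508 with an estimated correlation). Of 7 leukocyte markers 4 were called higher (set adjusted p = 0.0842). S100a8 stood at 6.88 ± 1.71, and at 1.07 without combination replicate 2 (adjusted p = 0.456), and its call also ended without any TNF replicate (adjusted p = 0.0565 to 0.0712). It lay between 1.53 and 1210 CPM within the combination group, the highest in replicate 2, the library with 1890 CPM of leukocyte markers. Among the lists without a call, death receptor and apoptosis genes had 2 of 19 lower and 1 higher, the TNF receptor complex 2 of 18 lower, adhesion molecules and metalloproteases 3 of 13 lower and 1 higher, checkpoint ligands 2 of 8 lower, TGF-beta and matrix genes 3 of 14 lower, and cell cycle genes 1 higher and 1 lower. The test called 1500 genes, 491 higher and 1009 lower. The count was 954 without TNF replicate 1, 756, 751 and 905 without combination replicate 1, 2 or 3, 967 without the libraries that stood apart, 951 with the 6 libraries compared and 2634 with sample quality weights.

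**Figure D3:**
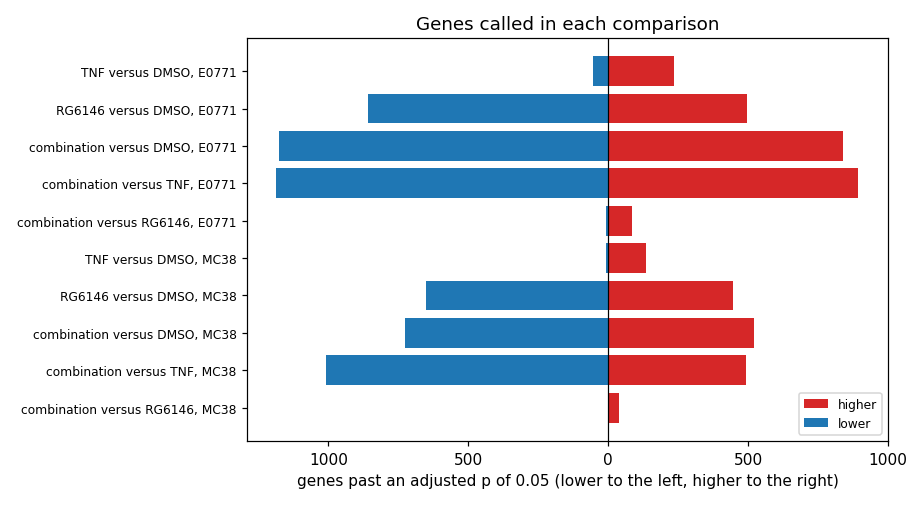
Bars give the genes past an adjusted p of 0.05 in each pairwise comparison, higher to the right in red and lower to the left in blue. The combination against TNF called 893 higher and 1186 lower genes in E0771 and 491 higher and 1009 lower in MC38, and the combination against RG6146 called 92 and 39 genes.

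To follow TNF-induced genes without choosing them in the libraries compared, the genes raised at least 2-fold by TNF in 1 line were tested in the other. Of the 79 genes chosen in E0771 and tested in MC38, 44.3% were lower with the combination than with TNF and 5.06% higher, against 7.38% lower among the other genes, with a median of -0.62. The set was lower than other genes with both correlations (camera p = 4.28e-14, and p = 0.00289 with an estimated correlation). Of the 95 genes chosen in MC38 and tested in E0771, 35.8% were lower and 15.8% higher, against 9.26% lower among other genes, with a median of -0.28 (camera p = 5.2e-05, and p = 0.129 with an estimated correlation). With an estimated correlation and no fold minimum, camera p was 0.0423 in E0771 and 0.0342 in MC38. With a log2 fold change of at least 2, camera p was 0.422 in E0771 and 0.0166 in MC38, so the result in E0771 depends on the minimum. The share lower in E0771 was 18% without the filter and 23.6% with DESeq2. In the line tested, TNF itself raised only 57 of the 95 genes in E0771 and 47 of the 79 in MC38 by call. For RG6146 against DMSO the medians of these sets were -0.07 in E0771 and -0.18 in MC38. Camera p was 0.432 and 0.0312, and 0.751 and 0.252 with an estimated correlation. A lower value with the combination than with TNF can therefore include an effect of RG6146 that needs no TNF. Sets chosen and tested in the same line had 59.2% lower in E0771 and 59.8% in MC38. With such sets, 20 simulations of unchanged groups against the shared TNF libraries called 0% lower by edgeR, with mean medians of -0.05 and -0.13, so the shared libraries alone pull the median down. The simulations drew each gene separately, with the same dispersion in all groups. They hold no deviation of a library shared across genes, so 0% is not a chance level for 59.2% and 59.8%.

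**Figure D4:**
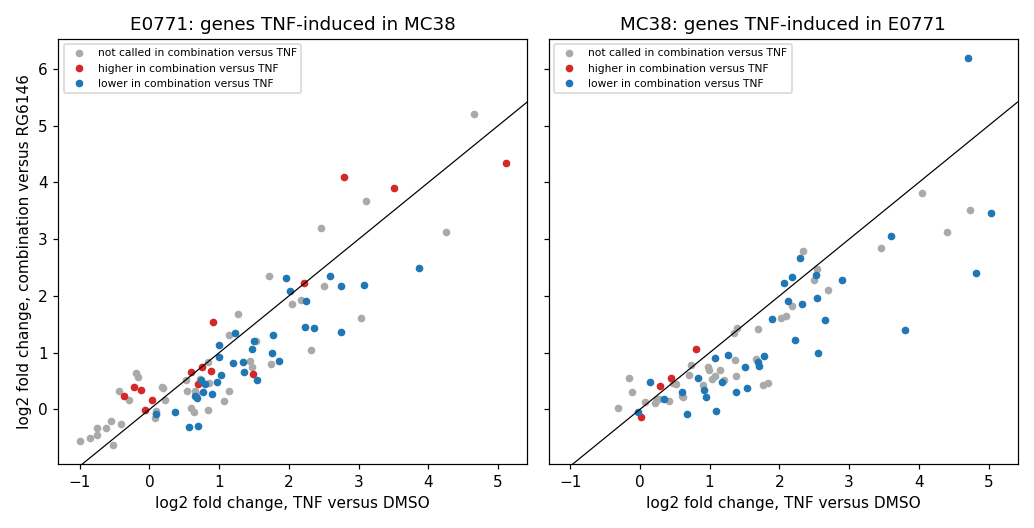
Each point is a gene raised at least 2-fold by TNF in the other line, with its log2 fold change for TNF against DMSO on the x axis and for the combination against RG6146 on the y axis, and the black line marks equal responses. Blue and red points are genes called lower and higher with the combination than with TNF, and 62 of 95 genes in E0771 and 63 of 79 in MC38 had the smaller response with RG6146.

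The comparison of the combination with RG6146 gave the TNF response of cells that also received the inhibitor. It called 92 genes in E0771, 85 higher and 7 lower, and 39 in MC38, 37 higher and 2 lower. In E0771 76 genes rose with TNF both with and without RG6146, against 1.6 for independent lists, and in MC38 34 against 0.379. Both comparisons share the estimate of the spread of their line, so 1.6 and 0.379 are not chance levels. NF-kB feedback regulators had 9 of 16 higher in E0771 and 4 of 16 in MC38 (15 and 13 adjusted over the list alone), and chemokines and cytokines 9 of 13 and 5 of 12 (10 and 8 adjusted over the list alone). Survival genes (3 of 13 and 2 of 14 higher), adhesion molecules and metalloproteases (3 of 14 and 1 of 13), immediate early genes (8 of 25 and 5 of 26) and p53 targets (3 of 16 and 1 of 17) rose as sets in both lines with both correlations. Adjusted over the list alone, 5 and 6 survival genes, 5 and 4 adhesion genes, 13 and 16 immediate early genes and 7 and 1 p53 targets rose, and 1 p53 target fell in E0771. In E0771 unfolded protein and stress response genes also rose as a set with 2 of 17 called, and the BET inhibitor-induced markers were lower as a set with 9 of 9 not called (adjusted p = 0.00936 and adjusted p = 0.0365 with an estimated correlation). Interferon-stimulated genes were higher as a set, with 2 of 28 and 1 of 27 called, in E0771 (adjusted p = 0.0136, and adjusted p = 0.0944 with an estimated correlation) and in MC38 (adjusted p = 5.15e-06, and adjusted p = 0.23 with an estimated correlation). TGF-beta and matrix genes were higher as a set with no member called in E0771 (adjusted p = 0.0237, and adjusted p = 0.0944 with an estimated correlation) and in MC38 (adjusted p = 0.0163, and adjusted p = 0.174 with an estimated correlation). In MC38, with no member called, mitochondrially encoded genes were lower as a set (adjusted p = 0.0179, and adjusted p = 0.23 with an estimated correlation) and leukocyte markers higher (adjusted p = 0.00177, and adjusted p = 0.235 with an estimated correlation), the latter with combination replicate 2 in the group. The counts were 58 and 57 without E0771 RG6146 replicate 1 or 3, 22, 18 and 23 without MC38 RG6146 replicate 1, 2 or 3, and 534 in E0771 and 62 in MC38 with the 6 libraries compared.

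The interaction asked whether the TNF response differed with and without RG6146. In E0771 it called 6 genes: Id2 at 1.04 ± 0.13, Phlda1 at 0.92 ± 0.12, Jun at 0.91 ± 0.13, Jund at 0.79 ± 0.12, Ptges at -1.22 ± 0.19 and Mmp9 at -1.95 ± 0.30 (adjusted p = 0.00961 to 0.03). None of the 6 was called without DMSO replicate 2 or 3, RG6146 replicate 1 or 3, or any combination replicate, 2 were without DMSO replicate 1 and 1 without RG6146 replicate 2, and 11, 8 and 11 genes were called without TNF replicate 1, 2 or 3. With the replicate number as a block 2 of the 6 were called, and the calls of Jun, Jund, Ptges and Mmp9 ended (adjusted p = 0.0862 to 0.123). As sets, adhesion molecules and metalloproteases had a smaller (1 of 14 called) and mitochondrially encoded genes a more positive TNF response with RG6146 (13 of 13 not called; adjusted p = 0.0468 and adjusted p = 0.0468 with an estimated correlation). For the mitochondrial genes, the TNF group held replicate 2, with 0.376% mitochondrial ribosomal RNA and 0.899% of counts in mitochondrial coding genes, against 1.066% to 1.228% in the other E0771 libraries. Immediate early genes were higher with 3 of 25 called (adjusted p = 0.000422, and adjusted p = 0.291 with an estimated correlation) and the MYC and ribosome biogenesis list lower with 30 of 30 not called (adjusted p = 0.0178, and adjusted p = 0.132 with an estimated correlation). In MC38 edgeR called 0 genes, with 772 at an unadjusted p under 0.05, limma-voom also called 0, DESeq2 2, and edgeR without the filter on low counts 211. Ccl2 stood at -2.42 ± 0.76 and Nfkbia at -0.61 ± 0.17 (adjusted p = 0.818 for both). The lower sets in MC38, with no member called, were NF-kB feedback regulators (adjusted p = 0.00819, and adjusted p = 0.156 with an estimated correlation), chemokines (adjusted p = 0.0268, and adjusted p = 0.182 with an estimated correlation), survival genes (adjusted p = 0.0156, and adjusted p = 0.156 with an estimated correlation), antigen presentation (adjusted p = 0.000752, and adjusted p = 0.0539 with an estimated correlation) and p53 targets (adjusted p = 0.0122, and adjusted p = 0.152 with an estimated correlation). Leukocyte markers were higher (adjusted p = 0.000132, and adjusted p = 0.182 with an estimated correlation), with combination replicate 2 in the group. On simulated data this test recovered 24.3% of changes of 1 and 71.3% of changes of 2 on the log2 scale in MC38, against 53.8% and 93.3% in E0771.

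Against DMSO the combination called 2015 genes in E0771, 839 higher and 1176 lower, and 1247 in MC38, 522 higher and 725 lower. The shares higher were 41.6% and 41.9%, and 24% and 29.3% with library totals alone, which moved the median of all genes in E0771 by -0.116. In E0771 the count was 1291 without combination replicate 2 and 3173 without TNF replicate 2, which shares in the estimate of the spread. With the 6 libraries compared it was 3852, nearly balanced at 1895 higher and 1957 lower. In MC38 it was 739, 772 and 748 without combination replicate 1, 2 or 3. The share higher in MC38 was 48.7% with RLE size factors, and the balance reversed with DESeq2 (743 higher and 679 lower) and without the filter (1010 and 793). The effect of RG6146 overlapped with and without TNF: 408 genes rose and 651 fell in both comparisons in E0771, against 35.4 and 81.3 for independent lists, with r = 0.769 across genes, and 247 rose and 435 fell in MC38, against 16.5 and 49.5, with r = 0.598. Genes are not independent replicates. These comparisons share no library, but both come from 1 fit of a line and share its estimate of the spread. The values for independent lists are therefore not chance levels.

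Against DMSO, NF-kB feedback regulators had 10 of 16 higher with the combination in E0771, and 7 higher and 1 lower of 16 in MC38 (12 higher and 1 lower, and 10 and 1, adjusted over the list alone). Chemokines and cytokines had 7 of 13 higher in E0771, and 4 higher and 1 lower of 12 in MC38 (9 higher, and 6 higher and 2 lower, adjusted over the list alone). Both lists, the adhesion, immediate early, BET inhibitor-induced and stress response lists rose in both lines with both correlations, and interferon-stimulated genes fell in E0771, 12 of 28 lower and 1 higher. In MC38 survival genes (2 of 14 higher and 2 lower) and BET and P-TEFb components (3 of 16 higher and 1 lower) were also higher as sets and fibroblast markers lower (2 of 4) with both correlations (largest adjusted p = 0.0479 with an estimated correlation). In E0771 BET and P-TEFb components were higher (adjusted p = 0.014, and adjusted p = 0.0693 with an estimated correlation) and cell cycle genes lower, 7 of 29 called (adjusted p = 0.014, and adjusted p = 0.124 with an estimated correlation). In no comparison was a list called where its median, mean and test differed in sign. With the combination against DMSO such lists were survival genes and leukocyte markers in E0771, and the death receptor, MYC, p53 and TGF-beta lists in MC38. Others in E0771 were, among more, cholesterol synthesis and fibroblast markers with TNF, TGF-beta and matrix genes with RG6146 and with the combination against TNF, and leukocyte markers with RG6146 and with the combination against RG6146. In MC38 they were, among more, BET inhibitor-induced markers with TNF, the TNF receptor complex with RG6146, and the MYC, cell cycle and mitochondrial lists with the combination against TNF.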

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

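The tests of E0771 reads as a source, of the other combination replicates, of a smaller TNF response over the sets and of the orientation of the line splits were chosen only after the results were seen, and the others before. The measured values come first, then 3 patterns that were weighed.

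For TNF against DMSO, 20 of the genes taken by the naming rule responded differently in the lines, as the effect in E0771 minus that in MC38 (adjusted p in parentheses). Part of them were named because this same test called them. Their number therefore does not measure how often genes named elsewhere differ between the lines. More positive in E0771 were Vcam1 at 1.72 (5.24e-05), Tnfaip2 at 1.29 (5.24e-05), Ptges at 1.94 (1.62e-05), Mmp9 at 1.99 (0.0142), Ikbke at 2.18 (0.0291), Adora2b at 2.17 (0.000219) and Plekho2 at 1.38 (0.0278). Adora2b rose by 2.1 in E0771 and stood at -0.03 in MC38. More positive in MC38 were Lif at -5.99 (0.0176), Cyth1 at -3.25 (0.0394), Cxcl10 at -1.85 (0.00469), Birc2 at -1.55 (0.0164), Dusp1 at -1.45 (0.0242), mt-Nd6 at -1.38 (0.0176), Gadd45b at -1.16 (0.0246), Ier5 at -0.91 (0.0209), Jun at -0.79 (0.0394), Ccdc71l at -2.00 (0.0394), Mrpl27 at -1.96 (0.0278), Ubqln2 at -1.86 (0.0242) and Tob1 at -1.85 (0.0457). Birc2 stood at 0.08 in E0771 and rose by 1.68 in MC38, and Lif at -0.17 and 5.87. Of groupings of the libraries drawn at random within lines, 12 of 100, the real grouping included, called at least the real 29 genes (highest other 732). Of those that set the lines opposite 9 of 49 did (highest 711), and these keep the response the lines share, so the count of 12 does not decide about chance. Of those that set the lines alike 2 of 50 reached 29 (highest 732), a share above 0.05 once the real grouping is added, so chance is not excluded. A regrouping with 732 calls points to a structure of the samples, and which one was not tested.

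For RG6146 against DMSO, 15 of the genes taken by the rule responded differently. Here too, part of them were named because this same test called them. More positive in E0771 were Igf2bp3 at 3.90 (0.0419), Rnf122 at 2.28 (0.0208), Slc4a11 at 2.16 (0.0165), Tubb3 at 2.09 (0.00286), Chd5 at 1.83 (0.00743), Tspoap1 at 1.72 (0.00871) and Hist1h1c at 0.87 (0.00606). More positive in MC38 were Sh2d5 at -2.39 (0.000139), Ereg at -1.97 (6.49e-05), Il20rb at -1.82 (0.00286), Rprd2 at -1.39 (0.00245), Smcr8 at -1.28 (0.0181), Nab2 at -1.28 (0.00828), Tnfaip8 at -1.06 (0.0151) and Bcl2l11 at -1 (0.0193). Igf2bp3 did not pass the filter in E0771. Of the groupings 10 of 100, the real one included, called at least the real 54 genes (highest other 341). Of those that set the lines opposite 9 of 49 did (highest 341), and these keep the response the lines share, so the count of 10 does not decide about chance. Of those that set the lines alike 0 of 50 reached 54 (highest 32), and 42 called no gene. These groupings mix RG6146 and DMSO libraries in at least 1 line, so the treatment effect enters the spread within groups and can lower the calls. They therefore do not decide about chance either.

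MC38 combination replicate 2 held transcripts of other cells. Of 16 detected leukocyte markers 14 were higher there than in each other MC38 library, which fits RNA of leukocytes, and S100a8 was at 1200, S100a9 at 580 and Lyz2 at 56.3 CPM of the raw library total. The markers summed to 9.19 times the highest E0771 library, which excludes E0771 reads as their only source, yet 29 genes restricted to E0771 stood at a median of 8.26% of their E0771 level, against at most 0.322% in other MC38 libraries, which fits some E0771 reads or RNA. The lower of the other 2 combination replicates reached 0.171 times the highest MC38 library without the combination, which excludes a shared response to the treatment. Which sample the leukocyte RNA came from was not tested.

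E0771 TNF replicate 2 and MC38 DMSO replicate 2 deviated from their groups alike, with r = 0.826 over 7668 genes, against a median absolute r of 0.158 over 144 pairs of libraries from the 2 lines. GC content and length are excluded as the whole cause, since r was 0.802 after both were regressed out. With all libraries thinned to the smallest total r was 0.806. Thinning keeps the make-up of each library, so it addresses only the noise of sampling and leaves open a bias that goes with depth. The 2 libraries had the largest totals of their lines, 9132814 and 9673118, and the least mitochondrial ribosomal RNA, 0.376% and 0.609%. The third replicates of the same groups had r = 0.778 and the first 0.64. The deviations of the 3 libraries of a group sum to 0 for each gene, so these 3 values are not independent. They do not decide whether replicate numbers match between the lines. A pair with different numbers, E0771 DMSO replicate 1 and MC38 DMSO replicate 3, had r = 0.608. No test addressed why these libraries deviated alike. No label names a batch, and no biological explanation was tested. Hence TNF against DMSO in both lines, and their difference, may carry this shared deviation (r = 0.826). Other comparisons use 1 of these libraries and may be affected too. They are the combination against TNF in E0771, RG6146 and the combination against DMSO in MC38, the line difference for RG6146 and the interactions.

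In the fits of 12 libraries TNF called fewer genes with RG6146 than without it. In E0771 the order depends on the setting: with only the 6 libraries compared TNF called 110 genes without and 534 with RG6146 (MC38 69 and 62), and with sample quality weights 289 and 370 (MC38 142 and 117). Sampling noise from unequal depth is excluded as the whole cause in the fits of 12 libraries. With every library thinned to 5392406 counts the lowest ratio of calls without to calls with RG6146 was 2.79 in E0771 and 3.79 in MC38. Unthinned, the ratios were 3.16 and 3.72. Thinning keeps the make-up of each library, so a bias that goes with depth stays open. A smaller TNF response over the genes chosen in the other line stays open in both lines: the interaction's camera p with an estimated correlation was 0.0613 in E0771 (median -0.23, 62 of 95 genes negative) and 0.00649 in MC38 (median -0.36, 63 of 79), camera p = 0.0229 and 0.0975 with no fold minimum, and camera p = 0.745 and 0.0747 with a log2 fold change of at least 2. More spread in the groups compared was given no test, but chi-square per degree of freedom between replicates measures it. In E0771 it was 1.62 to 3.22 with RG6146 and 1.95 to 3.14 with the combination. It was 2.34 to 5.97 with DMSO and 13.5 to 47 with TNF. These values argue against more spread with RG6146 as the cause in E0771. In MC38 the ranges were 6 to 17.7 and 8.88 to 11.3, against 14.5 to 38.1 and 2.13 to 31.7. They overlap, so more spread stays open there.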

How the results depend on the processing

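The 2 alternatives with libraries that stood apart left out and with sample quality weights were chosen only after the results were seen, and the other settings before. The limits are 3 libraries per group, of which the labels do not say that they were separate cultures, 1 time point and 1 dose, a growth protocol that names MC38-Ova for all samples, an unknown strand setting, and 4 libraries that stood apart. With groups of 3 an outlier rule could not be tested. No named gene reversed under the settings in which named genes were run, which leave out sample quality weights, and no list in the 5 settings run for lists.

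Without the filter TNF against DMSO called 524 genes in E0771 and 574 in MC38, the combination against TNF 2394 in MC38, the combination against RG6146 154 and 355, the interaction 27 and 211, the line difference 514 for TNF and 180 for RG6146, and the set share in E0771 was 18%. DESeq2 called 13 and 2 genes for the interactions, 305 for TNF and 66 for the combination against RG6146 in MC38, 182 and 129 for the line differences, and a set share of 23.6% in E0771. An estimated correlation left 71 of 302 list tests called, from 115. Sample quality weights called 3310 genes for RG6146, 4021 for the combination against DMSO, 370 for the combination against RG6146 and 13 for the interaction in E0771, 1659 for RG6146, 2634 for the combination against TNF and 117 for the combination against RG6146 in MC38, and 17 and 399 for the line differences. With only the 6 libraries compared the counts in E0771 were 110 for TNF, 3108 for RG6146, 3852 for the combination against DMSO, 881 against TNF and 534 against RG6146, and in MC38 69 for TNF and 735, 951 and 62 for the combination against DMSO, TNF and RG6146. Without the libraries that stood apart they were 2333, 3173 and 156 in E0771 for RG6146, the combination against DMSO and against RG6146, 967 in MC38 for the combination against TNF and 116 for the RG6146 line difference. Sets chosen in the same line gave 59.2% in E0771.

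Counts with 1 library left out were taken only for libraries of the groups compared, although all 12 libraries of a line share in the estimate of the spread. Without E0771 TNF replicate 2, RG6146 called 2333 genes, the combination against DMSO 3173 and against RG6146 156, all outside the ranges that follow. Leaving out 1 library of the groups compared at a time gave 164 to 622 genes for TNF, 728 to 933 for RG6146, 1291 to 1478 for the combination against DMSO, 1266 to 2898 against TNF and 57 to 69 against RG6146 in E0771, and 0 to 11 for the interaction. In MC38 it gave 95 to 160, 479 to 1243, 739 to 1097, 751 to 1195 and 18 to 27 in the same order, and 0 throughout for the interaction. The line differences ranged from 7 to 327 and 24 to 88, and the set shares from 27.1% to 42.1% in E0771 and 31.3% to 47.4% in MC38. Of 3096 tests of named genes with 1 library left out 438 lost their call and 8 gained one. Of 426 results of named genes in a comparison, calls lost were 12 with DESeq2, 18 with limma-voom, 13 with library totals, 4 with RLE size factors, 10 without the filter, 32 with the block and 37 without the libraries that stood apart, and 55 of 330 with only the 6 libraries compared.

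With the replicate number as a block the E0771 interaction called 2 genes and the RG6146 line difference 32, and the cause was not tested. Within the lines the numbers do not pair the samples: of 18 same-numbered pairs 5 in E0771 and 7 in MC38 had r over 0.1, with means of -0.035 and -0.036, and 20 of 72 best matches were with the own number. Between the lines this was not tested as a whole. Same-numbered libraries of E0771 TNF and MC38 DMSO had r = 0.826, 0.778 and 0.64, values that are not independent because the deviations of a group sum to 0.

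For comparisons of 2 groups of 3 the 10 possible splits are too few for a share under 0.05. The real split was 1 of 10 and the highest other 0 for each: 291, 1357, 2015, 2079 and 92 genes in E0771 for TNF, RG6146, the combination against DMSO, TNF and RG6146, 145, 1098, 1247, 1500 and 39 in MC38, and set shares of 35.8% and 44.3%. For the E0771 interaction 1 of 100 splits, the real one, reached 6 genes (highest other 2). The other splits mix libraries of different treatments, so treatment effects enter the spread within groups and can lower the calls. The splits therefore do not decide about chance for that count. The block left 2 genes, and 7 of the 12 fits with 1 library left out called 0. For MC38 100 of 100 reached the real 0, and the highest called 24.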

Other observations

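The test of gene length was chosen before the results were seen, and no test in this part only after.

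Some changes with RG6146 lay outside the lists. In E0771 Tspoap1 (2.96 ± 0.19), the cyclin gene Ccno (2.83 ± 0.33) and Tubb3 (2.74 ± 0.19), a neuronal tubulin gene, rose against DMSO, and Eya1 (-2.14 ± 0.29) and Zbtb45 (-2.17 ± 0.35) fell. In MC38 Apon (2.57 ± 0.38) rose.

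A hypothesis was that the effect of RG6146 over 3 h depends on gene length, with long genes lowered more. Spearman's rho of gene length with the log2 fold change was -0.095 for RG6146 against DMSO and -0.031 for the combination against TNF in E0771, and -0.003 and -0.166 in MC38. For TNF against DMSO in MC38, which shares the TNF libraries with the comparison at -0.166, it was 0.204. The value nearest to 0, -0.003, leaves the hypothesis undecided. Reads from 3′ ends can miss loss within long genes, which was not tested.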
